A study of Escherichia coli with 45 samples.

How the data were processed

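Total RNA from 45 cultures was depleted of ribosomal RNA and sequenced, 3 biological replicates per series text in each of 15 groups (5 strains, 3 conditions). Per the labels, cells were grown to an OD600 of 0.3 and treated with 0.35% (v/v) MMS for 30 min at 37 °C, with AKG at 25 mM in the third condition. The labels give no time, temperature or shaking for the untreated cultures, so a matching 30 min without MMS is not known. The submitters' notes name BWA (7.16v and 7.6), StringTie and DESeq2 without their settings, and give no genome build, read length or read number. Values of DESeq2 were not used here. Each library has a file for 3842 mRNA loci and a file for 816 noncoding features. The deposited TPM are transcript shares scaled within a library, and their sum over a file was not fixed. The deposited FPKM are fragments per kilobase scaled by library size. Both were made by the authors. Per the file headers there is also a coverage, the mean depth per base of a locus, and a read count column. That deposited read count equals coverage times locus length, so it is a number of bases and was not used as counts. TPM and FPKM stand in a constant ratio within a library.

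TPM summed to 960694 to 983262 over the mRNA loci. Over the noncoding features TPM summed to 712815 to 1276102, so FPKM was used there in place of the TPM first planned. Between 7 and 78 loci were listed at 0 per library. Of 3842 loci 469 were over 1.2 times as long as the gene they are named for and cover neighbours as well, and such values are given as a row. The umuD row spans umuC and the alkB row spans ada. Names were matched to an annotation of the MG1655 strain for 3828 loci, used for names and neighbours only. Noncoding names seldom matched their coordinates (1 of 721 within 1 kb, median distance 1412.1 kb), so features are named by place, with coordinates as the files give them. Of these features 40 overlap a listed locus, and all 816 are listed on the plus strand. Repeated lines in 32 of the noncoding files were merged.

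Values were divided by median-of-ratios factors and log2 transformed after adding 1. Loci with a mean of at least 1 TPM over the libraries of a fit were tested with limma 3.58.1 (empirical Bayes with trend and robust settings, R 4.3.3, statmod 1.5.0), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Only the groups compared entered a fit, 6 libraries for each of 18 pairs of mRNA groups and 12 for each interaction. There were 26 mRNA comparisons, MMS against untreated and MMS with AKG against MMS in each strain, each mutant against WT without and with MMS, and the difference of each mutant's MMS or AKG response from that of WT, plus 2 noncoding ones in WT. Comparisons with WT and interactions share the WT libraries, so overlaps between them were not counted. Fold changes are on the rescaled scale, and group means are of the deposited TPM. Rescaling shifted the MMS fold changes of WT by 0.37 and those of the noncoding features by 0.68. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures made with matplotlib 3.10.9.

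Gene lists fixed before the values arrived were tested with fry, which tests direction on balance and does not compare a list with other genes, adjusted over the 26 lists of a comparison. Beside it stand camera, which compares a list with the other genes under an estimated correlation between genes, and counts adjusted over the list alone. Values given with an estimated correlation are those of camera. As camera and fry ask different questions, the part of the correlation in a call lost with camera was not separated. The lists, with members tested of members listed, were SOS (31 of 32), Ada (3 of 4), other DNA repair (25 of 29), heat shock (18 of 18), OxyR (11 of 11), SoxRS (13 of 15), RpoS (14 of 15), acid resistance (14 of 14), TCA cycle without fum genes (11 of 14), glyoxylate shunt (5 of 5), C4-dicarboxylate and 2-oxoglutarate transport with fumarate respiration (10 of 12), respiratory chain and ATP synthase (22 of 28), glycolysis (14 of 14), ribosomal proteins (51 of 54), flagella and chemotaxis (32 of 38), nitrogen assimilation (12 of 17), cysteine and sulfate assimilation (9 of 16), methionine (11 of 12), arginine (11 of 11) and histidine synthesis (2 of 8), iron uptake (19 of 25), iron-sulfur cluster assembly (11 of 13), cold shock (5 of 6), e14 prophage (13 of 19), toxin-antitoxin pairs (11 of 18) and small RNAs (29 of 30). The histidine list thus rests on 2 members.

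Genes named in the report follow a rule set in advance. They are the fum genes, a panel (recA, lexA, sulA, umuD, umuC, dinI, recN, uvrA, uvrB, polB, dinB, ada, alkA, alkB, aidB, kgtP), and the 8 highest and 8 lowest fold changes in WT comparisons (4 and 4 elsewhere) among called loci with groups apart and a mean of at least 10 TPM in the higher group. From each called list the 2 to 4 members that changed most were added. Groups apart was not asked of interactions.

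Precision was read from the replicates. The median SD of log2 values over the 2972 loci used for it lay between 0.063 and 0.151 in 13 groups, and was 0.488 in untreated fumB and 0.495 in untreated fumAB. The pipeline was tested on simulated data made from the real libraries. In the MMS comparison of WT a log2 change of 0.5 was found for 46 of 67 genes, of 1 for 62 of 67 and of 2 for 65 of 66, with 7 false calls among 3372. In the fumA interaction these were 38 of 67, 55 of 67 and 66 of 66, with 17 false calls among 3566. Most genes were left unchanged in these simulations (3372 of 3572 and 3566 of 3766). In the real data 3129 of 3766 loci were called for MMS in WT, and 1821 loci in the fumA interaction. The rates were thus not tested under so wide a change, and they were not split by TPM level.

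Alternatives named before the data were examined were a replicate block, other scalings (none, quantile), other filters (none, 10 TPM), a pseudocount of 0.1, FPKM for TPM, limma without trend or robust settings, a single fit over all 15 groups, leaving out each library in turn, and leaving out the 4 libraries whose label and deposited name disagree. The fit without the 4 libraries was likewise a single fit over all 15 groups. Replicate numbers were checked for pairing between groups. Every correlation of a pair of groups was over 0.1 in 13 of 38 pairs of groups (median 0.394). On average over the other groups, 30 of 45 libraries correlated most with libraries of their own number. This called for pairing in 5 of 18 two-group comparisons, whose blocked counts are given beside the main ones, and splits that part all pairs gave at most 0 loci. Labels were never changed.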

Results

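RNA was sequenced from Escherichia coli BW25113 (WT) and from 4 mutants labelled as deletions of fumarase genes, fumA, fumB, fumA with fumB (fumAB), and fumA with fumC and fumB (fumACB). Fumarases interconvert fumarate and malate. FumA and FumB are iron-sulfur enzymes and FumC is an iron-free one. Each strain was left untreated, treated for 30 min with methyl methanesulfonate (MMS, which methylates DNA), or treated with MMS while alpha-ketoglutarate (AKG) was present at 25 mM. AKG is an acid of the tricarboxylic acid (TCA) cycle and the co-substrate of AlkB, which repairs methylated bases. The 15 groups had 3 libraries each, which the series text calls biological replicates, so fold changes below have n = 3 libraries per group unless libraries are said to be left out. Reads over annotated loci came to 0.708 to 11.3 gigabases per library (median 2.51), which is a mean coverage of 170.1 to 2709.7. Ribosomal RNA held 0.0430% to 4.82% of the summed abundance (in TPM, scaled transcript shares). The labels name a medium with AKG and a phosphate buffer of pH 6.8, and do not say which other cultures had that buffer. Values given for added AKG are thus for the medium with AKG, and a part of the buffer in them was not separated. The labels also do not say whether untreated cultures were incubated for a matching 30 min. A part of that incubation in the values given for MMS was not separated.

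Levels of the fum genes were read in each library as a check on the strains. In untreated WT, fumA had 316 ± 3.13 TPM (mean ± SD), fumB 141 ± 4.26 and fumC 39.9 ± 1.01. The libraries labelled fumA had 0.512 ± 0.128 TPM of fumA without treatment. The libraries labelled fumACB had 0.103 ± 0.0760 TPM of fumC and 36.3 ± 4.70 of fumA, while fumB was at 162 ± 7.67 and did not differ from WT (log2 fold change -0.13 after rescaling, adjusted p = 0.108). Under MMS, the libraries labelled fumAB had 0.392 TPM of fumA and 6.42 ± 0.386 of fumB, against 14.9 ± 1.43 of fumB in WT. The libraries labelled fumB had 1.51 ± 0.185 TPM of fumB and 52.9 of fumA under MMS. Without treatment the picture for these last mutants was mixed. The library labelled fumB had 0.188, 707 and 0.279 TPM of fumA in replicates 1, 2 and 3, and the library labelled fumAB had 769, 0.597 and 714. For replicates 1 and 3 of both groups, 4 libraries in all, the deposited names give the other of these strains. The flagellin gene fliC, picked after its values were seen, split the same libraries, at 31.5, 14970 and 38.2 TPM under the fumB label and 14030, 38.9 and 15000 under the fumAB label. Comparisons that use untreated fumB or fumAB libraries were run as labelled. Some counts and values are also given from a fit without these 4 libraries, which leaves 1 untreated library for each of these mutants. That fit takes in all 15 groups at once. Its calls and counts thus differ from the main ones by the fit as well as by the libraries. In replicate 2 of untreated fumAB, where label and deposited name give one strain, fumB was at 54.1 TPM, beside 39.6 ± 5.12 in untreated fumA and 5.77 in replicate 2 of untreated fumB.

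**Figure D1:**
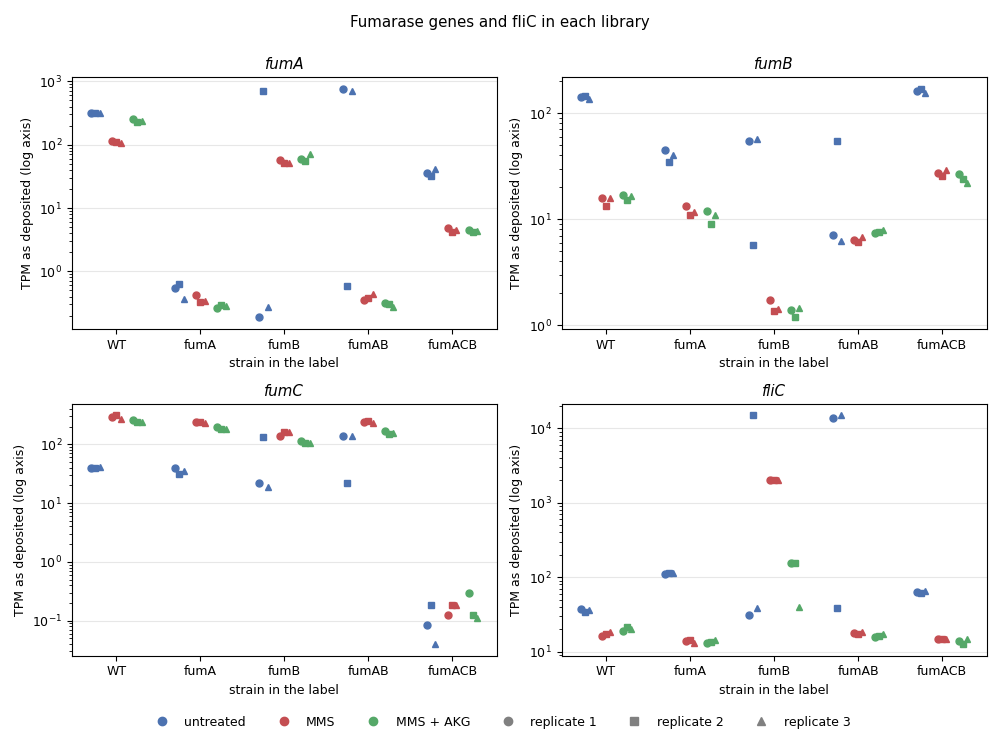
TPM of fumA, fumB, fumC and fliC in each of the 45 libraries, by the strain on the label. Marker shape is the replicate number and colour is the treatment; n = 3 libraries per group.

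Under MMS, WT cells raised genes of alkylation repair, the SOS response, sulfate assimilation, and the heat shock and oxidative stress regulons. Genes of fumarate respiration and central carbon metabolism fell. No list call for MMS in WT held with camera, written here as with an estimated correlation (lowest adjusted p = 0.264). Camera sets a list against the other genes, most of which changed here, so a list that rose in full can miss it. The largest fall was in tdcB, a threonine dehydratase (log2 fold change -9.44 ± 0.07 SE, 5.16 TPM against 3334 untreated, adjusted p = 2.64e-11). Next came the tryptophanase leader tnaC (-9.32), the tryptophanase gene tnaA (-9.10 ± 0.06, 34.4 against 14807 TPM, adjusted p = 2.45e-11) and the tryptophan transporter gene tnaB (-8.68). Trehalose uptake gene treB fell by 8.63 (19.7 against 6248 TPM), followed by the neighbours of tdcB, tdcC (-8.19), tdcD (-8.00) and tdcA (-7.96). Among the largest rises were cysI (7.39 ± 0.24, 973 against 3.70 TPM, adjusted p = 2.54e-07, in a row that also covers a neighbour), cysD (7.02), cysH (6.67) and cysC (5.64), all of sulfate assimilation, and sbp (6.95), a sulfate-binding protein. Aerobic glycerol-3-phosphate dehydrogenase gene glpD (6.61, 1603 against 11.6 TPM), bdcA (6.37) and the stress outer membrane gene bhsA (6.27, 2738 against 26.3 TPM) also rose. The fum genes parted, as fumA fell by 1.90 ± 0.07 and fumB by 3.55 ± 0.09 while fumC rose by 2.43 ± 0.07 (adjusted p = 2.59e-08, 4.38e-09 and 7.43e-09).

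DNA repair genes answered MMS by regulon. All 3 measured genes of the Ada regulon, the adaptive response to alkylation, rose (median log2 3.31). They were alkB (5.26 ± 0.10, 1473 against 28.3 TPM, adjusted p = 7.95e-10), alkA (3.31 ± 0.12, 167 against 12.1 TPM) and aidB (1.70). The alkB row of the files also spans ada, so its value is for both genes. Of 31 SOS genes 27 rose and 2 fell (median 1.29), among them recX (5.16), tisB (4.23), dinI (4.10), sulA (3.65 ± 0.07, 1305 against 77.7 TPM) and recA (2.36 ± 0.10, 4008 against 590.2 TPM, adjusted p = 7.72e-08). Smaller rises were in the umuD row (2.65), recN (3.27), dinB (1.79), uvrB (1.65), uvrA (1.54), polB (1.19) and the SOS repressor lexA (0.55). Other DNA repair genes went both ways, 11 up and 8 down of 25 (10 and 8 adjusted over the list alone), and that list was not called (adjusted p = 0.575, with a median of -0.05 and a test direction of up). SOS and Ada lists were called by the list test (adjusted p = 4.58e-06 and 5.60e-06), and each had adjusted p = 0.264 with an estimated correlation.

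Protein and redox stress genes rose with them. All 18 heat shock genes rose (median 2.39), led by the small chaperones ibpA (5.64) and ibpB (5.51). All 9 measured genes of cysteine and sulfate assimilation rose (median 4.83, adjusted p = 3.28e-06), as did 10 of 11 OxyR genes (1.54), with the glutaredoxin gene grxA (5.14), trxC (4.73), ahpF (3.61) and the catalase gene katG (2.20). In the SoxRS list 10 of 13 rose (1.04), with marA (5.24) and soxS (4.86), and all 11 genes of iron-sulfur cluster assembly rose (1.39), with iscR (4.84). Each of these lists had adjusted p = 0.264 with an estimated correlation. Ribosomal protein genes rose in 39 of 51 cases and fell in 4 (median 0.77, adjusted p = 3.68e-05, and 0.264 with an estimated correlation). The e14 prophage list rose (0.61, 7 of 12 up, adjusted p = 0.00406, and 0.432 with an estimated correlation), and so did methionine synthesis (0.44, 6 up and 3 down of 11, adjusted p = 0.00227, and 0.779 with an estimated correlation), where metF led (2.01).

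Many metabolic genes fell. C4-dicarboxylate transport and fumarate respiration fell in 9 of 10 genes (median -4.43, adjusted p = 1.72e-06, and 0.264 with an estimated correlation), with dcuC (-6.70), frdB (-5.89) and the aspartase gene aspA (-5.85). TCA cycle genes outside the fum genes fell in 10 of 11 cases (-1.43; 0.449 with an estimated correlation), with sucC (-3.32) and mdh (-3.21), all 14 glycolysis genes fell (-1.86; 0.429), and 18 of 22 respiratory genes fell (-1.60; 0.449), with cydA of the bd oxidase (-5.33). RpoS-dependent genes fell in 11 of 14 cases (-0.80; 0.264), with wrbA (-4.78) and osmE (-3.61), and acid resistance in 11 of 14 (-1.46; 0.264), where the cadaverine exporter gene cadB rose (2.95). Flagella and chemotaxis fell in 22 of 32 (-0.84; 0.264), cold shock in 4 of 5 (-1.46; 0.429) although the helicase gene deaD rose (2.18), the glyoxylate shunt in 4 of 5 (-0.75; 0.730), and both histidine genes fell (-0.96; 0.449). Toxin-antitoxin pairs had 4 of 11 down and 1 up (-0.21, adjusted p = 0.0279, and 0.860 with an estimated correlation), and their median was 0.19 without rescaling. Signs differed for arginine synthesis (median -0.04, test up, adjusted p = 0.00637, and 0.860 with an estimated correlation) and iron uptake (median 0.29, test down, adjusted p = 0.00235, and 0.884), where feoB fell (-4.12) and fhuF rose (2.32). The median for iron uptake was -1.71 when loci under 10 TPM were left out, and arginine synthesis then had 0.48. Nitrogen assimilation (median 0.31, test down, adjusted p = 0.151) and small RNAs (-0.18, test up, adjusted p = 0.566) were not called.

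In all, 3129 of 3766 loci differed between MMS and no treatment in WT (limma, adjusted p under 0.05), 1579 up and 1550 down. Without rescaling it was 1946 up and 1195 down. The libraries did not overlap for 3197 loci (84.9%), where chance would give 10%. Counts adjusted over the list alone were equal to those above for the 25 lists other than DNA repair.

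Under MMS the mutants moved many of the same genes as WT. The lists of alkylation repair, SOS, heat shock and sulfate genes were called up in every strain, and tnaA, tnaC and treB fell by at least 8.12 in each. None of the list calls under MMS held with an estimated correlation, where the lowest adjusted p was 0.163 in fumA, 0.0682 in fumB, 0.0831 in fumAB and 0.198 in fumACB. In the fumA strain tnaA fell by 10.40 and the maltose-binding protein gene malE by 9.45, while ibpB rose by 8.50 ± 0.13 (2331 against 5.62 TPM, adjusted p = 3.35e-10) and ibpA by 7.49. The fumACB strain lost most in glpT (-9.41 ± 0.08, 2.96 against 2599 TPM, adjusted p = 9.85e-12), treB (-9.05), the glpA row (-8.995) and gatA (-8.41), and gained most in ibpB (8.62 ± 0.08) and bhsA (7.77). Largest falls in the fumB strain were tnaC (-9.27) and tnaA (-9.20), and in the fumAB strain tnaA (-10.67), with ibpB the largest rise in both (7.86 and 7.70). Without the 4 libraries tnaA fell by 10.77 in fumB and 9.04 in fumAB. The Ada regulon rose in full in fumA (median 2.63), fumB (2.78), fumAB (2.66) and fumACB (2.55). Values for alkB were 5.71, 5.59, 5.64 and 5.87 in that order, for recA 2.16, 2.73, 2.48 and 2.41, and for sulA 3.35, 3.42, 3.56 and 3.00. Those of fumB and fumAB use the 4 libraries. Without them fumB and fumAB had 5.64 and 5.44 for alkB, 2.28 and 3.00 for recA, and 3.14 and 3.90 for sulA. The rise of recA was then lower in fumB than in fumAB. SOS genes rose in 25, 25, 26 and 27 of 31 cases (medians 1.32, 1.41, 1.59 and 1.16). The repressor gene lexA fell slightly in the fumA strain (-0.17, adjusted p = 0.00826), a direction that turned to 0.31 with quantile normalization.

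Heat shock genes rose in 18 of 18 cases in each mutant (medians 3.44, 3.01, 2.50 and 3.01), and cysteine and sulfate genes in 9 of 9 (3.92, 3.69, 4.31 and 3.98). In fumA and fumACB, ribosomal protein genes rose (1.65, 48 of 51, and 0.85, 45 of 51), as did iron-sulfur cluster assembly (2.72 and 2.81, 11 of 11 each) and iron uptake (0.81, 13 up and 6 down of 19, and 1.55, 14 up and 4 down). TCA cycle genes fell (-2.76, 10 of 11, and -1.73, 9 of 11), as did all 14 glycolysis genes (-1.20 and -1.72) and flagella and chemotaxis (-1.86, 31 of 32, and -1.50, 27 of 32). RpoS genes fell in the fumA strain (-0.78, 11 of 14), and in fumACB had a median of 0.15 beside a test direction of down. Transport gene kgtP, which takes up AKG, rose in WT (0.62, adjusted p = 2.96e-05) and fell in fumA (-1.31) and fumB (-1.16, adjusted p = 0.0153, and -0.52 without the 4 libraries). It was not called in fumAB (-0.55, adjusted p = 0.205), where it fell by 1.21 without the 4 libraries, and its fall in fumACB (-0.36) turned to 0.24 with quantile normalization.

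Loci called numbered 3249 in fumA (1642 up), 2028 in fumB (1041 up), 2072 in fumAB (1074 up) and 3261 in fumACB (1636 up). The counts for fumB and fumAB rest on mixed untreated libraries, and were 3131 and 3035 without the 4 libraries. Blocking by replicate, which the fumA libraries called for, gave 3276 in fumA. WT, fumA and fumACB share no libraries, and 1223 loci rose and 1212 fell in all of them, against 287 and 285 expected for independent sets of those sizes. In all 5 strains 798 rose and 746 fell (21.3 and 19.9 expected).

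**Figure D2:**
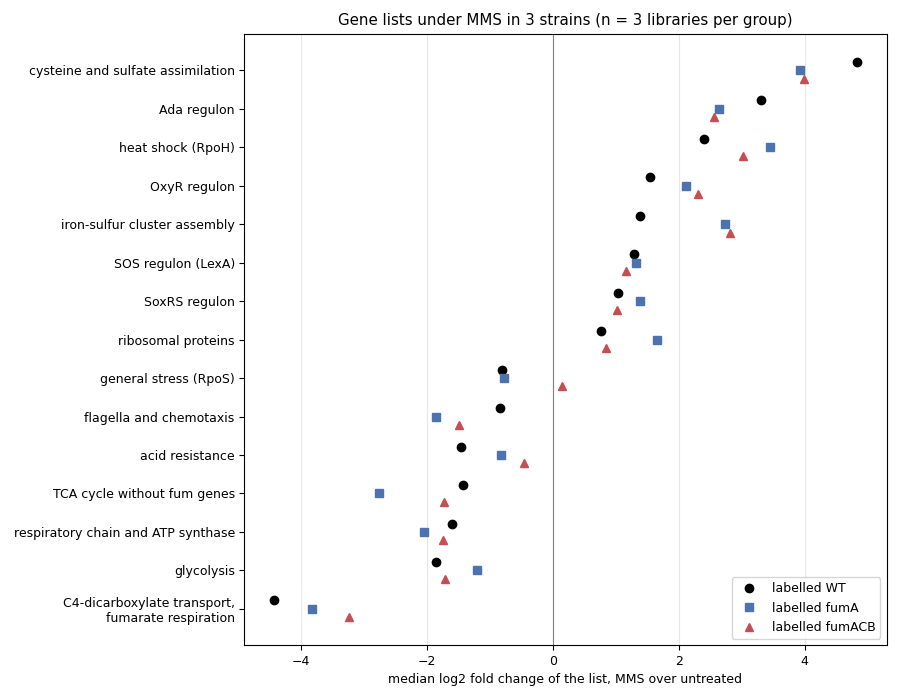
Median log2 fold change under MMS of 15 lists in WT, fumA and fumACB. All points passed the list test (adjusted p under 0.05); none passed with an estimated correlation; n = 3 libraries per group.

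The response to MMS also differed between the mutants and WT. By the list test heat shock genes responded higher and sulfate genes lower in each mutant, in few genes of the fumAB strain. Of these heat shock and sulfate calls only that of sulfate genes in fumB held with an estimated correlation (adjusted p = 0.0238). Over all 26 lists 1 call held in fumA, 2 in fumB, 1 in fumAB (adjusted p = 0.0147) and 1 in fumACB. The gene glpD, already high in untreated fumACB, fell there (-2.56) while it rose in WT, where the glpA row did not change (0.05, adjusted p = 0.690) and glpT fell (-0.76). In untreated fumAB replicate 2, where label and deposited name give one strain, glpD was also high, at 1512 TPM. It was at 1672 and 1437 in the 2 libraries labelled fumB whose deposited names give fumAB, and at 603 in fumAB under MMS. All 4 comparisons of a mutant with WT use the same WT libraries. In the fumACB strain the response of glpD differed from WT by -9.15 ± 0.11 (adjusted p = 4.54e-14), that of the glpA row by -9.01, glpT by -8.61 and yzgL by -7.46. Higher than in WT were the responses of sufA (4.03), an iron-sulfur scaffold gene, and of yhjX (4.27), a transporter gene of the pyruvate response. For the fumA strain the lowest were the astE row (-5.46 ± 0.15) of arginine breakdown, aldA (-4.81) and putP (-4.64), and the highest ydhY (4.999) and yhjX (4.75). Untreated levels enter some of these differences. Without MMS the astE row was already higher and ydhY lower in fumA than in WT. The glpA row and glpT were likewise already higher in untreated fumACB, while yhjX was higher in fumA and fumACB under MMS itself. Heat shock differences had medians of 1.37 in fumA (17 of 18 higher), 1.18 in fumB (7 higher, 1 lower; 11 and 1 adjusted over the list alone), 0.84 in fumAB (3 and 3; 9 and 3 adjusted over the list alone) and 1.10 in fumACB (15 of 18). With an estimated correlation those lists had adjusted p = 0.203, 0.258, 0.572 and 0.254. Without the 4 libraries the medians were 0.73 in fumB and 0.66 in fumAB, and those of sulfate genes -1.59 and -1.05. For ibpB the difference was 2.98, 2.38, 2.19 and 3.12 in the same order. The ibpB values for fumB and fumAB use the 4 libraries. Without them its rise under MMS was 8.53 in fumB and 7.10 in fumAB.

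Cysteine and sulfate genes responded less in fumA (median -0.44, 7 of 9 lower; adjusted p = 0.292 with an estimated correlation), fumB (-1.36, 7 of 9; 0.0238), fumAB (-0.52, 1 of 9; 0.555) and fumACB (-1.38, 8 of 9; 0.254). Iron uptake genes responded more in fumA (0.87, 13 of 19; 0.382 with an estimated correlation) and fumACB (1.54, 17 of 19; 0.0758), with entC of enterobactin synthesis 3.46 higher in fumACB. This list was not called in fumB (0.00, adjusted p = 0.962) or fumAB (0.69, adjusted p = 0.561), and without the 4 libraries it was called higher in fumB (1.86) and lower in fumAB (-1.64). In the fumA strain flagellar genes fell further than in WT (-1.18, 28 of 32 lower, 30 adjusted over the list alone), and with an estimated correlation adjusted p was 0.0129. Their list medians (log2) were 4.17 to 4.35 in untreated WT, 5.02 to 5.10 in untreated fumA and 4.64 to 4.685 in untreated fumACB. Under MMS they were 2.37 to 2.64, 2.40 to 2.58 and 2.54 to 2.71. The difference thus lay in the untreated levels, and the levels under MMS were alike. In fumACB 19 of 32 fell further (-0.64; 0.0555 with an estimated correlation) and 13 of 14 RpoS genes responded higher (1.15; 0.0201), with osmY at 2.87. The RpoS list medians (log2) were 7.24 to 7.47 in untreated WT and 6.01 to 6.13 in untreated fumACB. Under MMS they were 5.90 to 6.04 in WT and 5.50 to 5.71 in fumACB. The fumACB strain thus began lower and stayed below WT under MMS. The glyoxylate shunt responded lower in fumA (-1.75; 0.217 with an estimated correlation), fumB (-1.28; 0.301) and fumAB (-1.76; 0.0792) and was not called in fumACB (-0.17, adjusted p = 0.109). SOS genes as a list were not called in fumA (-0.04, adjusted p = 0.223), fumB (0.16, adjusted p = 0.869) or fumAB (0.05, adjusted p = 0.0793, and 0.11, adjusted p = 0.0357 without the 4 libraries), and were lower in fumACB (-0.22, 6 higher and 12 lower of 31, adjusted p = 0.00390, and 0.768 with an estimated correlation), a call that quantile normalization ended. The Ada list was not called in fumA, fumB, fumAB or fumACB (adjusted p = 0.277, 0.678, 0.782 and 0.809), and was higher in fumAB without the 4 libraries (0.15, adjusted p = 0.0399).

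Loci with a different MMS response numbered 1821 in fumA (963 higher, 858 lower), 984 in fumB (482 and 502), 563 in fumAB (275 and 288) and 2144 in fumACB (1065 and 1079). Without rescaling the same comparisons gave 458 higher and 1686 lower, 275 and 937, 191 and 521, and 632 and 1717. The counts of fumB and fumAB use the 4 libraries. The fit without them also takes in all 15 groups, so its counts do not show what leaving them out alone would change.

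Added AKG changed carbon, nitrogen, general stress and ribosomal protein genes of WT under MMS. The lists of RpoS-dependent genes, the TCA cycle, the glyoxylate shunt and nitrogen assimilation were called up, and kdpA and fecA were the lowest genes. Of 20 lists called 0 held with an estimated correlation (lowest adjusted p = 0.0855), and the SOS list was not called. The highest genes were csiD (2.53 ± 0.09, 29.0 against 4.03 TPM, adjusted p = 2.17e-07) and lhgO (2.06), which break down glutarate by way of AKG, with ymdF (2.50), the srlA row (2.31) and srlB (2.24) of sorbitol uptake, yciG (2.27), ybgS (2.08) and wrbA (2.00 ± 0.07, 218 against 51.9 TPM). The lowest were kdpA (-3.71 ± 0.21, 1.66 against 31.9 TPM, adjusted p = 5.39e-06) and kdpB (-1.95) of the high-affinity potassium pump, the ferric citrate receptor gene fecA (-2.12), azuC (-1.86), cadB (-1.77 ± 0.04, 120.5 against 400.6 TPM), ypdK (-1.74), ylaC (-1.49) and shoB (-1.48). AKG doubled fumA (1.04 ± 0.05, 237 against 111 TPM, adjusted p = 1.10e-06), left fumB unchanged (0.07, adjusted p = 0.600) and lowered fumC (-0.29).

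All 14 RpoS genes rose with AKG (median 1.49, adjusted p = 4.33e-06, and 0.0855 with an estimated correlation), with osmE (1.90), osmY (1.77) and katE (1.75). The glyoxylate shunt rose in 4 of 5 genes (1.07; 0.412 with an estimated correlation), with aceB (1.57) and aceA (1.52), and the TCA cycle in 9 of 11 (0.65, 10 adjusted over the list alone; 0.277), with sucC (1.09). Nitrogen assimilation rose in 9 of 12 (0.56; 0.178 with an estimated correlation), with the astE row (1.88) and the glutamine synthetase gene glnA (1.72), and arginine synthesis in 8 of 11 (0.58; 0.178). Glycolysis rose in 12 of 14 (0.29; 0.430), both histidine genes rose (0.37; 0.528), C4-dicarboxylate genes had 6 up and 2 down of 10 (0.34, 6 and 3 adjusted over the list alone; 0.584), respiratory genes 12 up and 4 down of 22 (0.21, 14 and 5 adjusted over the list alone; 0.621), and iron-sulfur cluster assembly 7 up of 11 (0.20; 0.584). Among repair genes the alkB row rose by 0.42 ± 0.06 (2038 against 1473 TPM, adjusted p = 0.000380), which carried the Ada list (0.18, 1 of 3 up, adjusted p = 0.0437, and 0.584 with an estimated correlation), a list call that ended without rescaling. The SOS genes recA (-0.01, adjusted p = 0.852) and sulA (0.01, adjusted p = 0.883) did not change, dinI fell (-0.55), and the SOS list was not called (-0.01, 6 up and 7 down of 31, adjusted p = 0.327).

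Lower with AKG were ribosomal proteins (-0.23, 43 of 51, 46 adjusted over the list alone; 0.277 with an estimated correlation), iron uptake (-0.22, 5 of 19; 0.277) with fhuF (-0.97), SoxRS genes (-0.15, 6 of 13; 0.277) with soxS (-0.92), and toxin-antitoxin pairs (-0.25, 3 of 11; 0.277) with the yoeB row (-0.98). Small shifts down were called for heat shock (-0.09, 9 of 18; 0.584), cold shock (-0.28, 2 of 5; 0.584) and OxyR genes (-0.05, 4 of 11; 0.584), and each of these calls ended without rescaling, where OxyR had a median of 0.00. Acid resistance had a median of 0.36 beside a test direction of down (adjusted p = 0.00262, and 0.858 with an estimated correlation). Flagella and chemotaxis (0.11, adjusted p = 0.0179, and 0.584) had a median of -0.01 when loci under 10 TPM were left out. Not called were cysteine and sulfate genes (0.11, adjusted p = 0.944), methionine (0.04, adjusted p = 0.817), e14 (-0.07, adjusted p = 0.291), other DNA repair (0.08, adjusted p = 0.0656) and small RNAs (0.02, adjusted p = 0.568). In all 1758 of 3799 loci changed (935 up, 823 down). In a single fit over all 15 groups, whose variance takes in the mixed groups, 716 did.

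**Figure D3:**
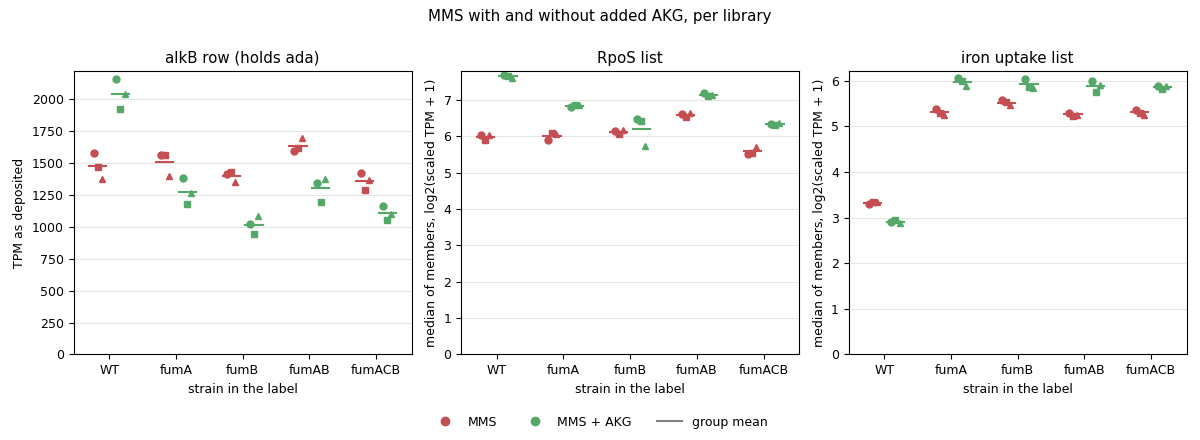
TPM of the alkB row (with ada) in each library under MMS and under MMS with AKG. The RpoS and iron uptake lists are shown as list medians (log2) in the same libraries. Marker shape is the replicate number and lines are group means; n = 3 libraries per group.

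In the mutants AKG had some effects in common with WT and some opposite to it. The potassium gene kdpA fell in every strain, and alkB, which rose in WT, fell in fumA, fumAB and fumACB. The iron uptake list was called down in WT and up in the 4 mutants, in 5 of 19 genes in WT and 8 to 14 in the mutants. None of these iron uptake calls held with an estimated correlation (adjusted p = 0.277 in WT and 0.156, 0.416, 0.0942 and 0.432 in fumA, fumB, fumAB and fumACB). Values for kdpA were -4.03 ± 0.16 in fumA, -3.61 in fumB, -3.31 in fumAB and -3.51 in fumACB (adjusted p = 1.20e-06, 1.69e-05, 6.25e-07 and 2.01e-06), and for fecA -2.95, -2.79 and -3.02 in fumA, fumAB and fumACB. The envelope stress gene cpxP rose in fumA (1.99), fumB (2.11) and fumACB (1.93). Lowest in the fumB strain were flagellar and chemotaxis genes, fliC (-4.28 ± 0.45, 116 against 2016 TPM, adjusted p = 0.00279), tsr (-3.85) and tar (-3.73), and proV rose there (2.21). AKG replicate 3 of fumB stood apart for fliC, at 39.3 TPM beside 155.7 and 153.7, and without it fliC fell by 3.72. In fumA the yhjX gene fell by 3.48 and cysH by 3.01, while malE rose (1.76). In fumAB the fimbrial gene fimA fell by 2.68, while ymgI (2.93), gatC (2.51) and malE (2.40) rose. In fumACB ymgG (2.06) rose and yhjX fell (42.3 against 175 TPM).

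Iron uptake genes rose by medians of 0.55 in fumA (14 of 19), 0.35 in fumB (8 up, 1 down), 0.27 in fumAB (13 of 19) and 0.23 in fumACB (9 up, 4 down), with entC at 1.29, 1.06, 0.86 and 0.82. Adjusted over the list alone 15, 12, 14 and 11 rose, and none of these calls held with an estimated correlation. RpoS genes rose in fumA (0.73, 13 of 14; 0.156 with an estimated correlation), fumAB (0.32, 9 of 14, 10 adjusted over the list alone; 0.0942) and fumACB (0.35, 9 of 14; 0.247), and were not called in fumB (0.24, adjusted p = 0.497). There replicate 3 with AKG stood apart, with a list median (log2) of 5.74 beside 6.47 and 6.41 in replicates 1 and 2 and 6.07 to 6.165 without AKG. Leaving it out, a test added after the data were seen, 12 of 14 rose in fumB (0.40, adjusted p = 0.000602). Cysteine and sulfate genes fell in full in fumA (-1.97, 9 of 9; 0.156 with an estimated correlation) and fumAB (-0.63, 9 of 9; 0.0942). They fell in fewer genes in fumB (-0.22, 3 of 9; 0.445) and fumACB (-0.15, 4 of 9, 5 adjusted over the list alone; 0.550). SOS genes fell on balance in fumA (-0.09, 5 up and 10 down of 31; 0.541 with an estimated correlation), fumB (-0.23, 7 down; 0.416), fumAB (-0.14, 5 and 12; 0.259) and fumACB (-0.17, 5 and 14; 0.432), and adjusted over the list alone 11, 11, 14 and 16 fell. The SOS calls in fumA and fumB ended without rescaling. The alkB row fell in fumA (-0.27, adjusted p = 0.00972), fumAB (-0.31, adjusted p = 0.000588) and fumACB (-0.27, adjusted p = 0.00221), and was not called in fumB (-0.40, adjusted p = 0.105, and -0.54, adjusted p = 0.000145 without AKG replicate 3).

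Tested against the WT response, with the same WT libraries in all 4 comparisons, iron uptake was higher in fumA (0.67, 16 of 19, 17 adjusted over the list alone), fumB (0.56, 11, and 15 adjusted over the list alone), fumAB (0.58, 16) and fumACB (0.41, 10, and 11 adjusted over the list alone). With an estimated correlation these calls held (adjusted p = 0.0134, 0.0232, 0.00429 and 0.0350). RpoS genes were lower (-0.69, 10 of 14; -1.26, 13; -1.14, 13; -1.07, 12), with katE at -1.17, -1.59, -1.44 and -1.63, and with an estimated correlation adjusted p was 0.0478, 0.330, 0.00429 and 0.00389. Nitrogen assimilation was lower too (-0.47, -0.48, -0.70 and -0.49; 0.0478, 0.186, 0.00908 and 0.0645 with an estimated correlation). Medians for the TCA cycle were -0.41, -0.85, -0.34 and -0.30 (0.180, 0.330, 0.161 and 0.364 with an estimated correlation). For glycolysis they were -0.39, -0.37, -0.68 and -0.48 (0.288, 0.422, 0.116 and 0.160). Sulfate genes were furthest from WT in fumA (-1.72, 9 of 9; 0.0478 with an estimated correlation). The alkB row was lower by 0.69, 0.83, 0.73 and 0.70 (adjusted p = 0.000166, 0.00215, 6.46e-06 and 2.19e-05), and alkA by 0.44, 0.74, 0.61 and 0.60 (0.00868, 0.0110, 0.000127 and 0.000115). Both fliC in fumB (-4.47) and yhjX in fumA (-3.91) and fumACB (-2.44) were lower, as was csiD in fumAB (-2.12) and fumACB (-2.22). Without AKG fliC was at 17.2 TPM in WT and 2016 in fumB, so it could fall little in WT. For cpxP the difference was 1.95, 2.06 and 1.88 in fumA, fumB and fumACB.

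AKG changed 1296 loci in fumA (642 up), 358 in fumB (137 up), 1568 in fumAB (784 up) and 1532 in fumACB (761 up, and 1600 with replicates blocked, which these libraries called for). Over WT, fumA and fumACB, which share no libraries, 268 rose and 241 fell in all (31.3 and 28.7 expected), and over 5 strains 60 and 65 (0.200 and 0.300 expected). Responses differed from WT for 964 loci in fumA (360 higher), 811 in fumB (269), 1458 in fumAB (625) and 1385 in fumACB (575). In a single fit over all 15 groups these were 130.0, 191, 238 and 262, and most iron uptake and RpoS calls ended there. The fumB count for AKG ranged from 133 to 1090.0 as single libraries were left out.

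Without MMS, the fumA and fumACB strains already differed from WT. In fumA, apart from the deleted gene (-7.83 ± 0.09), the lowest genes were ydhY (-4.44), ydhV (-3.60) and ynfE (-3.25), of anaerobic reductases, and fumB was lower (-1.98, adjusted p = 2.53e-06). The highest were the astE row (4.78 ± 0.11, 336 against 9.92 TPM), the sialic acid channel gene nanC (4.59), the acetate permease gene actP (4.49) and the paaE row (4.31), and kgtP was higher (1.42). In fumACB, fumC (-5.38), ydhY (-3.46), ygeW (-3.46) and fumA (-3.41) were lowest, and the glpA row (7.93 ± 0.11, 3950 against 12.1 TPM, adjusted p = 1.27e-08), glpD (6.70), glpT (5.73) and yfaH (5.67) highest. Flagellar genes were higher in fumA (1.24, 30 of 32; adjusted p = 0.0285 with an estimated correlation) and fumACB (0.90, 24 of 32; 0.113). Iron uptake was higher too (1.10, 16 of 19, 18 adjusted over the list alone; 0.381, and 0.51, 9 of 19; 0.470). The glyoxylate shunt was higher in fumA (1.05; 0.442) and lower in fumACB (-0.50; 0.691), and the TCA cycle was slightly higher in fumA (0.23, 4 of 11; 0.779) and lower in fumACB (-1.55, 11 of 11; 0.490). RpoS genes were lower in fumACB (-1.34, 13 of 14; 0.0997). Lower in both were C4-dicarboxylate genes (-0.77; 0.442, and -0.65; 0.376) and glycolysis (-0.50; 0.690, and -0.40; 0.777). SOS genes were slightly higher in fumA (0.18, 10 up and 5 down of 31; 0.551) and not called in fumACB (median -0.07, test up, adjusted p = 0.684).

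Loci called without MMS numbered 1518 in fumA (741 up) and 1822 in fumACB (861 up), and in a single fit over all groups 925 and 1150.0. Without rescaling they split as 1164 up and 452 down in fumA and 1734 and 472 in fumACB. The untreated fumB and fumAB groups, which were mixed, gave 46 and 40 loci, among them nanC (3.78 and 4.06), nanM (3.33 and 3.65) and fliQ (2.95 and 3.20). Blocking by replicate gave 0 for both, and without the 4 libraries the counts were 1091 and 2656.

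Under MMS, the iron uptake and heat shock lists were called higher in every mutant than in WT, and cold shock and sulfate genes lower. With an estimated correlation the iron uptake calls held in fumB, fumAB and fumACB (adjusted p = 0.0191, 0.0456 and 0.0415) and no heat shock, cold shock or sulfate call did. These 4 comparisons also share the WT libraries. Iron uptake was higher by medians of 2.17 in fumA (18 of 19), 2.22 in fumB (19), 2.04 in fumAB (18) and 1.98 in fumACB (18), and with an estimated correlation adjusted p in fumA was 0.0844. The enterobactin gene entC was higher by 3.81, 4.09, 3.70 and 3.79 (79.1, 97.5, 81.2 and 86.1 TPM against 5.55), and the catecholate receptor gene cirA by 3.44, 3.57, 3.54 and 3.41. All 18 heat shock genes were higher (1.04, 1.16, 0.91 and 0.94; adjusted p = 0.0844, 0.0965, 0.0906 and 0.195 with an estimated correlation), with ibpB at 2.95, 3.15, 2.95 and 3.27. All 5 cold shock genes were lower (-1.34, -1.48, -1.27 and -1.71; 0.311, 0.105, 0.223 and 0.242 with an estimated correlation). Sulfate genes were lower in 9, 9, 7 and 9 of 9 cases (-0.59, -1.44, -0.64 and -1.28; 0.311, 0.105, 0.275 and 0.242), and TCA cycle genes were lower (-0.50, -0.62, -0.49 and -0.79; 0.311, 0.105, 0.223 and 0.195). In the fumB strain flagellar genes were far higher (3.15, 31 of 32; 0.0191 with an estimated correlation), with fliC at 6.96 ± 0.06 (2016 against 17.2 TPM, adjusted p = 1.95e-11), and sbp was 3.45 lower. The ribonucleotide reductase gene nrdA was lower in fumA (-2.29) and fumB (-2.78), and yhjX was higher in fumA (4.99) and fumACB (4.52).

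Among repair genes under MMS, alkA was lower in each mutant (-0.65, -0.87, -0.74 and -0.995; adjusted p = 3.46e-05, 1.91e-06, 2.78e-06 and 6.83e-07). The alkB row was higher in fumA (0.23) and fumAB (0.18, adjusted p = 0.0127) and did not differ in fumB (adjusted p = 0.137) or fumACB (adjusted p = 0.209), and its fumA call ended without rescaling. For recA the difference was -0.08 (adjusted p = 0.261), -0.17, -0.17 and -0.33. The SOS list did not differ in fumA (0.11, adjusted p = 0.131) or fumB (median -0.01, mean above 0, adjusted p = 0.677), was higher in fumAB (0.10, adjusted p = 0.0169, and 0.678 with an estimated correlation) and lower in fumACB (-0.16, adjusted p = 0.00227, and 0.625). The counts were 1947 in fumA (945 up), 2222 in fumB (1076), 2316 in fumAB (1119) and 2359 in fumACB (1128), and 939, 1285, 1290.0 and 1287 in a single fit over all groups. Blocked by replicate, as pairing called for in fumA, fumB and fumAB, they were 2016, 2256 and 2342. Without rescaling fumA had 528 up and 1595 down and fumB 740.0 and 1609.

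Noncoding features were compared in WT, and are named by their place because the deposited names did not match the coordinates. Under MMS the lowest lay between tnaC and tnaA (3881870 to 3882089, log2 -9.20 ± 0.30, 23.1 against 8487 FPKM, adjusted p = 1.19e-05), between wrbA and ymdF (-6.51), between xylE and malG (-6.15) and between aspA and fxsA (-6.11). Highest were the features between pyrL and yjgH (5.67 ± 0.23, 427 against 4.32 FPKM), between yjiC and iraD (5.09), between ompN and micC (4.68) and between dps and rhtA (4.49). With AKG the lowest lay between yjjL and yjjM (-3.90), cadB and cadC (-1.70), shoB and ohsC (-1.08) and argR and yhcN (-1.055). The highest lay on each side of ybdR (2.71 and 2.45), between rutB and rutR (1.93) and between ves and spy (1.87). MMS changed 374 of 780 features (197 up, 177 down; 308 and 94 without rescaling) and AKG 65 of 794 (45 and 20; 36 and 51 without rescaling, and 22 in all in a single fit over all groups).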

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

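Counting calls over other splits of the libraries was planned. Its expected outcomes, the splits with strain and treatment means removed and the second draw of splits came only after the results were seen. The refits set beside the alkB pattern were planned as alternatives, while their use as tests of it was chosen after the results were seen. The results below stand here because a test of the difference between a mutant and WT passed, for a count of loci or for a gene or list whose effects went opposite ways.

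The response to MMS differed from that of WT for 1821 loci in fumA, 984 in fumB, 563 in fumAB and 2144 in fumACB. The fumB and fumAB counts use the 4 untreated libraries whose label and deposited name disagree. The splits below were not run without them. Drawn splits of the 12 libraries numbered 100, the real one included. In fumA 1 gave as many loci (highest other 697) and in fumB 2 (highest other 1001). In fumAB it was 1 (highest other 263) and in fumACB 2 (highest other 2218). These shares are under 0.05, which argues against chance. They do not exclude it, as another split called more loci than the real one in fumB and fumACB. For fumB and fumAB the real split also rests on labels that the fumA levels exclude. With strain and treatment means removed, 2, 2, 1 and 2 of 100 splits gave as many (highest other 1999, 1672, 1 and 2350). In a second draw of 50 splits, 2, 1, 1 and 1 gave as many (highest other 1873, 406, 263 and 821), and 1 in each mutant with means removed (highest other 4, 0, 0 and 0).

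The response to AKG under MMS differed from that of WT for 964 loci in fumA, 811 in fumB, 1458 in fumAB and 1385 in fumACB. Of 100 drawn splits 6 gave as many in fumA (highest other 2685), 3 in fumB (highest other 1438), 7 in fumAB (highest other 2930) and 7 in fumACB (highest other 2182). By this count the share was under 0.05 for fumB only, so chance stays open for fumA, fumAB and fumACB. The other splits that called as many exchanged strains in 1 treatment only, which points to a structure of the samples, the difference between strains. With strain and treatment means removed 1 of 100 splits gave as many in each mutant (highest other 115, 1, 21 and 2), which argues against chance. These splits took the libraries as independent, although replicate numbers went together between some of the groups. A second draw of 50 gave 4, 4, 5 and 2 as large (highest other 2685, 1630.0, 1946 and 2145), which moved fumB and fumACB across a share of 0.05. With means removed it gave 1 each (highest other 2, 0, 9 and 2).

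The SOS repressor gene lexA rose by 0.55 under MMS in WT and fell in fumA (-0.17), a difference of -0.72 (adjusted p = 7.59e-06), while with quantile normalization it rose in fumA. In the fit without the 4 libraries whose label and deposited name disagree, the lexA difference in fumAB was -0.71. The transporter gene kgtP rose by 0.62 in WT and fell in fumA (-1.31, difference -1.93, adjusted p = 1.01e-09), fumB (-1.16, -1.75, 0.00304) and fumACB (-0.36, -0.95, 2.21e-07), the last not with quantile normalization. In fumAB kgtP was not called as labelled (-0.55, adjusted p = 0.205, difference -1.15, 0.0501), and without the 4 libraries it fell by 1.21 (difference -1.86). The toxin-antitoxin list had a median of -0.21 under MMS in WT and 0.26 in fumA, with a median difference of 0.93 (fry adjusted p = 0.000197; 0.429 with an estimated correlation). It was at 0.47 in fumB (difference 1.39, 0.00173; 0.483), 0.31 in fumAB (0.99, 0.00861; 0.572) and 0.30 in fumACB (0.87, 0.000205; 0.508). The WT median of this list was above 0 without rescaling (0.19) and with quantile normalization (0.25).

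With AKG, kgtP rose by 0.16 in WT and was lower in fumA (-0.23, difference -0.38, adjusted p = 0.000441), fumB (-0.53, -0.70, 0.000262), fumAB (-0.19, -0.35, 0.000208) and fumACB (-0.57, -0.72, 1.02e-06). In a single fit over all 15 groups none of these kgtP differences passed (0.591, 0.111, 0.564 and 0.0834), nor did those of the iron uptake list. Iron uptake genes had a median of -0.22 in WT, against 0.55 in fumA (difference 0.67, fry adjusted p = 3.77e-07), 0.35 in fumB (0.56, 5.87e-06), 0.27 in fumAB (0.58, 7.98e-08) and 0.23 in fumACB (0.41, 3.65e-06). Glycolysis genes stood at 0.29 in WT, -0.36 in fumAB (difference -0.68, 5.91e-07; 0.116 with an estimated correlation) and -0.19 in fumACB (-0.48, 5.65e-06; 0.160). Respiratory chain genes were at 0.21 in WT, -0.23 in fumA (difference -0.15, 6.78e-05; 0.204), -0.05 in fumAB (-0.06, 0.000254; 0.403) and -0.13 in fumACB (-0.14, 0.000528; 0.481). Heat shock genes were at -0.09 in WT, 0.01 in fumAB (difference 0.18, 0.000920; 0.336) and 0.15 in fumACB (0.19, 0.000599; 0.349).

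Flagellar genes were at 0.11 with AKG in WT and -2.13 in fumB (difference -2.14, fry adjusted p = 0.000543; 0.330 with an estimated correlation), and the list of C4-dicarboxylate transport at 0.34 and -0.11 (-0.55, 0.000113; 0.290). Under MMS without AKG the flagellar list stood at 2.37 to 2.64 (log2) in WT and 5.47 to 5.56 in fumB, so WT had little room to fall. In AKG replicate 3 of fumB the flagellar list median was 3.57 (log2) beside 4.44 and 4.48, and without that library the difference was -1.81 (8.60e-09). The Ada list had a median of 0.18 in WT, -0.31 in fumAB (difference -0.61, 0.000800; 0.360) and -0.27 in fumACB (-0.60, 0.00162; 0.505). In fumACB ribosomal protein genes were at 0.14 against -0.23 in WT (difference 0.36, 1.50e-05; 0.0817), and toxin-antitoxin genes at 0.18 against -0.25 (0.46, 0.000120; 0.0817).

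The alkB row, which spans ada, rose by 0.42 with AKG in WT and fell in fumA (-0.27, difference -0.69, adjusted p = 0.000166), fumAB (-0.31, -0.73, 6.46e-06) and fumACB (-0.27, -0.70, 2.19e-05). Rescaling of the TPM is argued against, since without rescaling or with quantile normalization the difference nearest to 0 over the 4 mutants was -0.56. A single deviating library is argued against, since 48 of 48 fits that left out 1 library kept the call. Reads of alkB and of its neighbour ada in this row cannot be told apart, since 0 loci of the files hold ada apart from alkB. A difference between the strains stays open, untested for either gene alone.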

How the results depend on the processing

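All alternatives were planned except list tests with each library left out for AKG in fumB, which were chosen after the results were seen. Counts stayed within 1.5 times the reported one in 397 of 472 checks, named genes kept direction and side of the threshold in 34035 of 35992, and lists in 1926 of 2274. Other scalings, filters, pseudocount, FPKM and limma without trend kept every count within 1.5 times. The check with FPKM could change little, since FPKM and TPM stand in a constant ratio within a library and rescaling removes it. Its 26 count, 2122 gene and 233 list checks are part of the totals above. Camera, which sets a list against the other genes and estimates a correlation between genes, ended 181 calls among 233 list results. What part the correlation had in this was not separated. A single fit over all 15 groups moved 21 of 28 counts, and the cause was not tested. AKG counts became 716 in WT, 386 in fumA, 354 in fumAB and 408 in fumACB, and 22 noncoding features in WT. Untreated counts against WT became 925 in fumA, 2247 in fumB, 1007 in fumAB and 1150.0 in fumACB, and under MMS 939, 1285, 1290.0 and 1287. In the same order MMS interactions gave 961, 1912, 1358 and 1241, and AKG interactions 130.0, 191, 238 and 262. With a replicate block limma called 0 loci in untreated fumB (899 at an unadjusted p under 0.05) and 0 in untreated fumAB (317), against 52 and 47 with limma without trend or robust settings and no block. Without the 4 libraries whose label and deposited name disagree, where the lone library left is assumed to vary like the other groups, the MMS count of fumB was 3131, untreated counts were 1091 in fumB and 2656 in fumAB, and MMS interactions 1739 and 2571. That fit takes in all 15 groups. A single fit with the 4 libraries kept gave 2247 and 1007 untreated and 1912 and 1358 for the MMS interactions of fumB and fumAB. The fit and the libraries left out thus both enter these counts. Without the 4, gene and list results gained a call or stayed on the same side of the threshold. Lists that gained one were MMS interactions, iron uptake in fumB (1.86) and fumAB (-1.64), and SOS (0.11) and Ada (0.15) in fumAB. Leaving out 1 library at a time, MMS counts spanned 1411 to 3153 in fumB and 1444 to 3242 in fumAB, the highest without untreated replicate 2 of each. The AKG count of fumB spanned 133 to 1090.0 (without MMS replicates 1 to 3: 156, 133 and 151; without AKG replicates 1 to 3: 202, 224 and 1090.0). Untreated fumB spanned 0 to 2479 (10, 2479 and 15 without its replicates 1 to 3) and fumAB 0 to 780.0 (10, 780.0 and 13). Each was 0 with limma without any WT replicate (1 to 3: 454, 447 and 447 loci at an unadjusted p under 0.05 in fumB; 253, 238 and 248 in fumAB). The MMS interaction of fumB spanned 536 to 2570.0 (without WT untreated replicates 1 and 3: 603 and 601; WT MMS 1 to 3: 577, 574 and 536; fumB untreated 1 to 3: 648, 2570.0 and 627; fumB MMS 1 to 3: 573, 540.0 and 542). That of fumAB spanned 331 to 1824 (WT untreated 1 and 3: 372 and 362; WT MMS 1 to 3: 350.0, 348 and 336; fumAB untreated 2: 1824; fumAB MMS 1 to 3: 349, 351 and 331). The AKG interaction of fumB spanned 609 to 1230.0 (highest without its AKG replicate 3). Among list tests for AKG in fumB, leaving out AKG replicate 3 brought calls of RpoS (0.40), Ada (-0.54) and nitrogen assimilation (0.06). The SOS call ended without AKG replicate 1 (adjusted p = 0.0563) or MMS replicate 2 (0.0613), and the sulfate call without MMS replicate 2 (0.0651). For its difference from WT, the Ada call ended in 8 of 12 such fits (adjusted p = 0.0542 to 0.0839), and ribosomal proteins gained a call without fumB AKG replicate 1 (0.39) or 3 (0.20). Noncoding MMS counts spanned 248 to 412 (248 and 249 without MMS replicates 2 and 3) and AKG counts 20 to 72 (without AKG replicates 1 and 2: 32 and 20; without MMS replicates 2 and 3: 25 and 30.0). Gene results reversed in 12 cases, and the cause was not tested. With quantile normalization these were lexA (0.31) in fumA and kgtP (0.24) and aceB (0.18) in fumACB for MMS, and pinE (-0.0549) in fumACB against WT under MMS. Without rescaling they were uvrA (0.0703) and dinB (0.0325) in untreated fumACB, dinI (-0.0082) and uvrA (-0.0151) in fumA under MMS, dcuA (-0.0113) in fumB under MMS, and fumC (-0.13), argG (-0.0328) and carA (-0.0252) in the MMS interaction of fumA. List medians reversed 9 times, and the cause was not tested. For MMS in WT these were arginine synthesis (0.32 without rescaling, 0.48 with a filter at 10 TPM), iron uptake (-0.0172 with quantile normalization, -1.71 with a filter at 10 TPM) and toxin-antitoxin pairs (0.19 without rescaling, 0.25 with quantile normalization). With AKG they were OxyR in WT without rescaling (0.0011), flagella in WT with a filter at 10 TPM (-0.0111) and nitrogen assimilation in fumACB without rescaling (-0.0082). Depth limits the loci with few reads, since the shallowest library had 0.708 gigabases over annotated loci against a median of 2.51. Read numbers were not used here, so no counting error can be set beside the deposited TPM.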

Other observations

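The genes in this paragraph, and all tests of the 2 patterns that follow them, were chosen only after the results were seen, while counts over other splits were planned. The proV row of osmoprotectant uptake rose with AKG under MMS by 1.98 in WT, 1.42 in fumA, 2.21 in fumB, 1.12 in fumAB and 1.59 in fumACB (adjusted p = 1.82e-07, 2.34e-06, 0.00528, 7.29e-06 and 9.29e-06). The gene proX rose by 1.57, 1.08, 1.31, 1.29 and 1.04, and spy by 1.66, 1.57, 1.195, 1.80 and 1.69 in the same order. The potassium pump gene kdpA rose with MMS by 2.44, 4.22, 2.82, 3.07 and 3.48, and fell with AKG by 3.71, 4.03, 3.61, 3.31 and 3.51. The labels do not give the cation of the AKG medium, so its part in these changes was not tested.

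The pyruvate response gene yhjX went different ways with AKG. It rose in WT (0.44, adjusted p = 0.00908) and fumAB (1.33, 2.06e-06), and fell in fumA (-3.48, 2.44e-08), fumB (-2.19, 0.00371) and fumACB (42.3 against 175 TPM, 5.75e-07). The differences from WT were -3.91, -2.63, 0.89 and -2.44 in fumA, fumB, fumAB and fumACB (adjusted p = 2.60e-10, 0.000139, 5.47e-05 and 3.22e-08). Of the glycerol phosphate genes, glpQ was higher in untreated fumACB than in WT (5.50, adjusted p = 1.14e-08) and fell there with MMS by 8.13, while sufA rose with MMS by 5.39 in that strain and by 1.39 in WT.

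The untreated libraries labelled fumB and fumAB divided across their labels into 2 sets. Depth or ribosomal RNA share that goes with the replicate number is argued against, since replicates of the other 13 groups differed by at most 0.503 (root mean square, log2). Drift of correctly labelled cultures is argued against, since fumA had at least 713.6 TPM in the 2 libraries labelled fumAB whose deposited names give another strain. An exchange of the labels of replicates 1 and 3 between these groups may be the source, as the smallest distance between strains by deposited name was 3.28 times the largest within a strain (1.438 against 0.439). The labels are excluded for these 4 libraries by their fumA levels. These were 768.8 and 713.6 TPM under the fumAB label and 0.188 and 0.278 under the fumB label. Under MMS fumA was at most at 0.433 TPM in the fumAB libraries and at least at 51.2 in the fumB libraries. Apart from drift, no biological explanation was tested.

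Without treatment fumB kept its WT level in libraries labelled fumACB, while under MMS it was at 27.2 TPM against 14.9 in WT, and fumA was left at 36.3 TPM untreated against 316 in WT. Reads of fumA assigned to its near copy fumB are argued against, since fumB had at least 3.74 times the TPM of fumA in each of the 3 untreated libraries. Reads of fumB assigned to fumA are argued against for what was left of fumA, since the lowest ratio of fumA to fumB there was 10.4 times the highest in the libraries labelled fumA. Whether fumB is intact in the strain, or part of it is transcribed without a product, cannot be told apart by its log2 difference from WT of -0.13, as values per locus do not show which bases were covered. The deletion named by the labels stays untested at this locus, and so for fumAB, with fumB at 54.1 TPM in untreated replicate 2.

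Other splits of 3 against 3 libraries number 10 with the real one, too few for a share under 0.05. For each count below 1 of 10 splits, the real one, gave as many loci. For MMS the real count and the highest other were 3129 and 0 in WT, 3249 and 0 in fumA, 2028 and 0 in fumB, 2072 and 0 in fumAB, and 3261 and 14 in fumACB. With AKG they were 1758 and 17, 1296 and 14, 358 and 0, 1568 and 0, and 1532 and 0 in the same order. Against untreated WT they were 1518 and 1 in fumA, 46 and 0 in fumB, 40 and 14 in fumAB, and 1822 and 14 in fumACB, and under MMS 1947 and 0, 2222 and 0, 2316 and 1, and 2359 and 17. For noncoding features in WT they were 374 and 0 with MMS, and 65 and 7 with AKG.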
